A study of Homo sapiens with 4 samples.

How the data were processed

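RNA immunoprecipitated with the methyltransferase NSUN2 was sequenced from PANC-1 cells, an established human pancreatic ductal adenocarcinoma line grown in medium with 10% serum. Cells received 30 mM sodium lactate or the water vehicle for 24 h. Per the labels' protocols, lysates in polysome lysis buffer were incubated for 4 h with an antibody against NSUN2 on protein A/G beads, and input RNA was taken before that step. RNA extracted with TRIzol went into libraries made with the SMART-Seq v4 kit, which amplifies full-length cDNA from small amounts of RNA. There were 4 libraries in 4 groups (vehicle input, vehicle IP, lactate input and lactate IP), with 1 library per group. No difference between groups therefore has a replicate check, no test across genes was run, and no p-value across genes is given.

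Per the submitters' processing notes, the tools included fastp 0.20.1, HISAT2 2.1.0, MACS2 2.2.7.1, bedtools 2.29.2, HOMER 4.11.1 and DiffBind (no version), with GRCh38 as the genome build. The tool that counted reads per gene, its use of strand, its treatment of reads that match several genes and the annotation release are not given in the sources used here. The authors deposited gene values in FPKM, fragments per kilobase of gene and per 1000000 fragments, without rescaling between libraries. The table held 24483 genes by Ensembl identifier, of which 4835 had no symbol, 14468 were protein-coding, 5537 were lncRNA genes and 2568 were processed pseudogenes. The authors also deposited 1 peak list per condition, each of an IP library against its own input, with a fold enrichment per peak as a ratio, a p-value and q-value, and their −log10 values, per the file headers. The smallest listed peak was 200 bp, and the largest listed p was 0.0496 in the vehicle list and 0.0498 in the lactate list. The fold and q of each peak are the authors' own and were used only to describe, rank or filter peaks within a list. A comparison of the IP libraries, deposited by the authors, gave for each peak a normalized read density (signal) in each library, the log2 ratio M of lactate over vehicle, the mean log2 density A and a column headed as a P value. That P never exceeded 0.25, and at 81.3% of peaks it equalled 0.5 times the binomial point probability of the rounded densities within 0.1%, so it is not a tail probability. It served here only as a score with fixed thresholds, and counts at P under 0.01 or 1e-05, or after Benjamini-Hochberg adjustment, carry no error rate. Its column names are those of the MAnorm program, which no source used here names, and its P rests on the reads of the 2 libraries, not the conditions.

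Whole reads behind the FPKM values were recovered. Ratios of low values between libraries, together with a whole-number product of gene length and library total, gave the totals, and the smallest whole numbers matching a gene's 4 values gave its reads. Of 72387 FPKM values above 0, 99.99% came out whole within 1e-06 reads. A factor common to all 4 libraries of a gene is lost in this step, so that reads of a gene can be understated and its length with them. The mitochondrial genes were set against RefSeq lengths, and MT-ND4 alone needed multiplying. Recovered lengths of 954 bp for MT-RNR1 and 1559 bp for MT-RNR2 equalled the RefSeq lengths. The recovered reads served for depth, for shares of reads with 95% Wilson intervals, and for 95% intervals on log2 ratios of reads. Reads of the authors' peak comparison were recovered from M and A, after taking off a line in A fitted at peaks of low A. At 113288 peaks with under 200 reads in each library, 100% came out whole within 0.02 reads. For peaks with more reads the same line was extended without this check. The kit adds no molecular identifiers, so intervals and floors cover counting error only.

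Gene changes are log2 ratios of FPKM + 1, which understates the change of genes with low values. Genes with FPKM of at least 1 in at least 1 of the compared libraries entered a comparison, and genes at a log2 ratio of at least 1 or at most −1 were counted. The 5 gene comparisons were lactate input over vehicle input, IP over input in vehicle cells, IP over input in lactate cells, lactate IP over vehicle IP, and the enrichment in lactate cells minus that in vehicle cells. A value relative to the median is the log2 ratio minus the median over all genes of that comparison. Intervals for named genes are on log2 ratios without a pseudocount, which are printed beside them. The 24 gene lists were fixed before the data were examined, as were the comparisons, thresholds, named-gene rule and most of the other settings tried. Each list with at least 3 measured members was placed by its median among 10000 random lists of the same size, matched on mean FPKM in 20 bins. This percentile describes these libraries, and lists under 2.5 or over 97.5 are called apart from the rest. Of 578 list symbols, 528 matched a gene of the table, and 14 genes stand on 2 lists.

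Named genes were the 10 highest and 10 lowest log2 ratios per comparison among protein-coding genes with a symbol, FPKM of at least 5 in at least 1 compared library and FPKM of at least 1 in each input. Named peaks were the 10 highest and 10 lowest M with P under 0.01, A at or above the median and a protein-coding symbol, 1 peak per gene. NSUN2, CDCP1 and STC1 were always named. From lists apart from the rest, up to 4 members were named, and from other lists up to 2. A gene that the rule for list members would name is not reported here. The lowest genes outside the mitochondrial genome, the peak in MT-RNR2, the abundant genes set beside their pseudogenes, and EGR1 and C6orf226 as the only coding genes at least 2-fold higher in the lactate input were singled out after their values were seen.

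Peaks of the conditions were called shared when they overlapped by at least 1 bp, without regard to strand, although the same strand had been planned. Alternatives for genes were pseudocounts of 0.1 and 5, no filter and FPKM of at least 5, scaling by median ratios over the 891 genes with FPKM of at least 5 in all libraries, scaling to equal totals without mitochondrial genes and the 20 highest genes, FPKM sums set to 1000000, protein-coding genes alone, and a threshold of 1.5-fold. Alternatives for peaks were stricter q, fold of at least 4, larger overlaps, equal numbers of peaks, and other thresholds on M and P. Constant scaling of the peak comparison and random lists matched on gene length were chosen after seeing the data. The latter lists were matched on gene length alone and not on mean FPKM. A call that changed with them can therefore stem from either. The constant scalings also used a binomial tail probability of the recovered reads in place of the deposited P. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used here.

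The steps were tested on simulated data. All 4 library totals were recovered, as were the true reads in every library for 96.2% of 17586 simulated genes. In the simulated comparison of the inputs, over 4463 genes with 50 genes changed at each size and direction, 100% of genes raised 4-fold and 86% of genes lowered 4-fold passed the threshold. At 2.67-fold, 80% of raised and 40% of lowered genes passed, against 0.0704% of unchanged genes. Of 300 random lists, 4.67% fell outside the percentile bounds. For the peak comparison, true reads were recovered at 100% of 20000 simulated peaks.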

Results

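RNA immunoprecipitation followed by sequencing was used to find RNA bound by NSUN2, an enzyme that places 5-methylcytosine (m5C) on RNA, in PANC-1 pancreatic cancer cells with and without lactate. The series title connects lactylation, a lactate-derived protein modification, with NSUN2, m5C and the growth of tumour cells along nerves. The 4 libraries were a vehicle input, a vehicle IP, a lactate input and a lactate IP, each from a single sample, so no value below has a replicate error and differences are described without a test. CDCP1, a transmembrane protein of cell adhesion and migration, and STC1, a secreted glycoprotein hormone, were followed as targets known from the study, beside NSUN2 itself.

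Recovered library totals were 17626197 reads in the vehicle input, 13620414 in the vehicle IP, 11175432 in the lactate input and 15189967 in the lactate IP. A single mitochondrial transcript, the large ribosomal RNA MT-RNR2, took most of the IP reads. Its share was 41.0% of the vehicle input and 68.0% of the vehicle IP, and 55.1% of the lactate input and 83.7% of the lactate IP. The small mitochondrial ribosomal RNA MT-RNR1 had 0.566%, 0.665%, 0.908% and 1.78% of reads in the vehicle input, vehicle IP, lactate input and lactate IP. Messenger RNA encoded by mitochondria went the other way, from 26.7% of the vehicle input to 0.457% of the vehicle IP and from 22.7% of the lactate input to 0.353% of the lactate IP. Nuclear genes kept 31.3% of the vehicle input and 30.3% of the vehicle IP, but 20.9% of the lactate input and 13.9% of the lactate IP. The 95% Wilson intervals of these shares were narrow (for MT-RNR2 in the lactate IP, 83.68% to 83.71%).

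**Figure D1:**
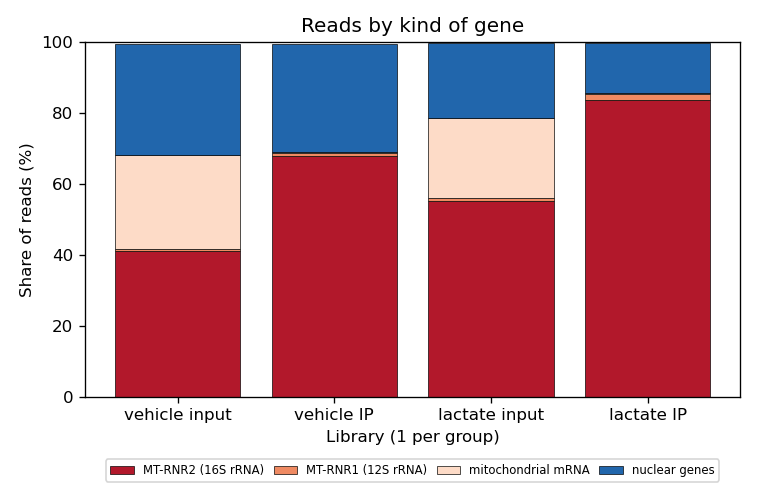
Percent of recovered reads (vertical axis) from MT-RNR2, MT-RNR1, mitochondrial messenger RNA and nuclear genes in each of the 4 libraries (1 stacked bar per library). Nuclear genes make up 13.9% of the lactate IP against 30.3% of the vehicle IP.

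Nuclear genes had 5511704 reads in the vehicle input, 4125848 in the vehicle IP, 2339172 in the lactate input and 2112574 in the lactate IP. The vehicle input thus held 2.36 times the nuclear reads of the lactate input, and the vehicle IP 1.95 times those of the lactate IP. Genes with FPKM of at least 1 numbered 6529, 8102, 5405 and 5646 in the same order, with a median of 264, 193, 145 and 157 reads. A count of 0 allows up to 3 reads, or 1.70e-05% of the vehicle input, 2.20e-05% of the vehicle IP, 2.68e-05% of the lactate input and 1.97e-05% of the lactate IP. Some processed pseudogenes had a higher FPKM than their parent gene, as PTMAP2 with 2135 against 1106 for PTMA and RPL3P4 with 224 against 14.4 for RPL3 in the vehicle input. How reads matching both were assigned is not given in the sources used here. GAPDH stood at only 6.23, with 263 reads against 23 for GAPDHP1 and 26 for GAPDHP65. Values of such genes, and of the overlapping pair MT-ATP6 and MT-ATP8, are uncertain.

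The inputs compare RNA levels after 24 h with lactate or vehicle. EGR1, an early growth response transcription factor, was higher in lactate cells, with FPKM 1.34 in the vehicle and 7.50 in the lactate input (74 and 263 reads). Its log2 ratio was 1.86, or 2.49 without a pseudocount (95% interval 2.11 to 2.88). DUSP6, a phosphatase that acts on ERK kinases, followed at 0.96, and CCN1 and CCN2, secreted proteins of the matrix, at 0.45 and 0.43. UBL5, a ubiquitin-like splicing factor, was lowest and went from FPKM 58.5 to 17.2 (log2 ratio −1.71, or −1.76 without a pseudocount with a 95% interval of −1.93 to −1.60), and the ATP synthase subunits ATP5F1E and ATP5PF stood at −1.59 and −1.56.

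The rest of the lowest genes were LGALS1 (galectin-1) at −1.60, TIMM8B (a mitochondrial import chaperone) at −1.57, NDUFA1 (respiratory complex I) at −1.52, SNRPG (a spliceosome core protein) at −1.50, LAMTOR2 at −1.46, AGR2 (a disulfide isomerase of the secretory pathway) at −1.42 and YAE1 at −1.41. The rest of the highest were the mitochondrially encoded MT-ATP8 at 0.53, MT-ND6 at 0.35 and MT-ND3 at 0.19, with PPDPF at 0.44, ESCO1 (a cohesin acetyltransferase) at 0.32 and IGF2R at 0.23. The median over 6766 genes was itself −0.43, and relative to it CDCP1 stood at 0.65, STC1 at 0.29 and NSUN2 at −0.19. For STC1 and NSUN2 the intervals without a pseudocount reached across the median (−0.18 to 0.83 and −0.60 to 0.03).

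Of the 22 lists with enough measured members, 6 lay above and 3 below the range of random lists in the inputs. Immediate early genes lay at percentile 99.98, with 1 of 9 members at least 2-fold higher and 0 lower, led by EGR1 and IER2 (0.55), CCN1 and CCN2. Osmotic stress genes lay at 99.15, with 0 of 7 members past 2-fold, 4 above the median gene and 3 below. NFAT5, the transcription factor of the osmotic response, and SLC5A3, a myo-inositol transporter, were 0.40 and 0.34 above the median gene, and the lowest member was at −0.29 from it. Mitochondrially encoded genes lay at 100, with 0 of 15 past 2-fold, and MT-RNR1 (0.68) and MT-RNR2 (0.43) among the highest. Nuclear long noncoding RNA lay at 99.2, with 0 of 11 past 2-fold and MALAT1 and NEAT1 at 0.00 and −0.03. Matrix and epithelial mesenchymal transition genes lay just past the bound at 97.535, with 0 of 15 past 2-fold and COL5A1 and TGFBI at −0.09 and −0.11. Vault and other small noncoding RNA lay at 99.99, with 2 of 6 members higher and 0 lower on very few reads, such as 1 and 14 for VTRNA1-1.

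Nuclear encoded oxidative phosphorylation lay at percentile 0.28 and held 37 measured members, of which 9 were at least 2-fold lower, 0 higher, and 33 under the median gene. Its median was −0.72, against −0.54 for its random lists matched on FPKM, which themselves lay under the median gene at −0.43. NDUFA1, COX6B1 (−1.39), COX7B (−1.30) and COX7A2 (−1.29) were the lowest. Histone genes that are transcribed with DNA replication lay at 0.57, with 2 of 7 lower, H4C3 at −1.26 and H1-2 at −1.13 on 43 and 8 reads. The integrated stress response, which slows translation and induces amino acid genes, lay at 1.09, with 1 of 16 lower, DDIT3 at −1.17, TRIB3 at −0.99, CHAC1 at −0.96 and PSAT1 at −0.88. Relative to the median gene, 1 member of the oxidative phosphorylation list and 0 of the histone and integrated stress response lists were at least 2-fold lower, and 1 mitochondrially encoded gene, MT-RNR1, was higher. The call ended for osmotic stress response (percentile 93.89), nuclear long noncoding RNA (79.4) and epithelial mesenchymal transition and matrix (89.94) with median ratios, and for integrated stress response (16.07) with pseudocount 5. With random lists matched on gene length and not on FPKM, chosen after seeing the data, it ended for vault and other small noncoding RNA (88.48) and replication dependent histone genes (6.025). The medians of all 9 of these lists kept their side of the median gene under each of the 3 other scalings.

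The other 13 lists stayed between the bounds in the inputs. Cytosolic ribosomal proteins had 5 of 73 members lower and 0 higher (RPL38 −1.31, RPL9 −0.20), the ductal identity list 3 of 14 lower and 0 higher (KRT18 −1.34, EPCAM −0.24), and glycolysis 2 of 9 lower and 0 higher (GAPDH −1.26, PGK1 −0.29). No member passed 2-fold among 6 m5C enzymes and readers (NSUN2 −0.62, ALYREF −0.39), 13 genes of lactate transport and lactylation (HDAC1 −0.86, EP300 −0.24), 9 hypoxia genes (ANGPTL4 −0.85, LOXL2 0.11), 9 oxidative stress genes (TXN −0.97, HMOX1 0.66) or 9 cholesterol genes (FDFT1 −0.78). The same held for 18 proliferation genes (AURKA −0.91, BUB1B −0.23), 9 interferon and inflammatory genes (ISG15 −0.72, CXCL8 0.36), 12 genes of nerve growth, axon guidance and perineural invasion (NTN4 −0.81), 12 messages described before as NSUN2 substrates (MYC −0.97, CCND1 −0.22) and 17 secretory and folding genes (HSPA5 −0.96, SDF2L1 −0.24). With random lists matched on gene length alone, cytosolic ribosomal protein genes (percentile 0), ductal adenocarcinoma and PANC-1 identity (0.22) and NSUN2 messenger RNA substrates described before (1.62) lay below the bounds. Nerve growth, axon guidance and perineural invasion (97.78) lay above them. The random lists here were not matched on FPKM, so the level of the genes as well as their length can give these calls. The perineural invasion list contains CDCP1 and STC1, taken from the study, and is not independent evidence of its direction. Relative to the median gene, 0 members of the ribosomal, ductal identity and glycolysis lists were at least 2-fold lower and 1 oxidative stress gene, HMOX1, was higher. On that scale the medians of the hypoxia, lactate and m5C lists changed side between scalings. Of 16 neuron and Schwann cell markers and 16 markers of fibroblast, endothelial and immune cells, 10 each were in the table and 2 each passed the FPKM minimum in the inputs, too few for a percentile.

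In all, 119 genes were at least 2-fold higher and 437 at least 2-fold lower in the lactate input, 21.4% of them higher. This split depends on the scaling, at 208 and 103 (66.9%) with median ratios and 192 and 101 (65.5%) with equal totals. Relative to the median gene it was 181 and 92 (66.3%). FPKM sets reads against all reads of a library, so a smaller nuclear share lowers the FPKM of nuclear genes at large. That share was 31.3% of the vehicle input and 20.9% of the lactate input. The median under 0 and the excess of lower genes as deposited therefore do not by themselves show less RNA in lactate cells. Among protein-coding genes 171 were lower and only EGR1 and C6orf226 higher, the latter at 1.33 on 1 and 11 reads. Short genes were lower than long genes, with medians of −0.66 over 489 genes of up to 2390 bp and −0.44 over 488 genes of at least 6644 bp.

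The IP of vehicle cells was set against its input to show which RNA was enriched in the NSUN2 IP. No library with a control antibody was analysed here. Enrichment over input, in either condition or in both, therefore cannot separate binding by NSUN2 from RNA carried along without it. The highest message was PRRC2C, a stress granule protein, with FPKM 6.53 in the input and 67.6 in the IP. Its log2 enrichment was 3.19, or 3.37 without a pseudocount (95% interval 3.30 to 3.45). Without a pseudocount RSAD1 (3.72) and ILRUN (3.42) lay above it. MAP1B, a microtubule-associated protein (3.09), MLEC, a lectin of the endoplasmic reticulum (3.08), BAZ1B, a chromatin remodelling factor (3.001), and ABCF1 (2.94) came next. CDCP1 was enriched at 2.04, from FPKM 3.13 to 15.997 (359 and 1418 reads), whereas STC1 stood at −0.29 (100 and 53 reads) and NSUN2's own message at −0.12 (329 and 228 reads). At the other end was MT-ND2, a complex I subunit, with FPKM 39128 in the input and 266 in the IP (−7.19). Outside the mitochondrial genome B2M, the light chain of class I histocompatibility molecules, was lowest at −4.68, from FPKM 351 to 12.7. This rank rests on the pseudocount, since without it LRRC40 (−6.80, 9 IP reads) lay under B2M (−4.79).

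RTF1 (2.90) and RSAD1 (2.87), the proliferation marker MKI67 (2.86), ILRUN (2.85) and NAT14 (2.81) completed the highest genes. The 10 lowest genes by the rule were all mitochondrially encoded, from MT-ND2 through MT-CYB (−6.88), MT-ND4 (−6.82), MT-ATP6 (−6.54), MT-ND1 (−6.23), MT-CO3 (−5.90), MT-ATP8 (−5.79), MT-ND6 (−5.51) and MT-ND3 (−5.41) to MT-ND5 (−4.83). After B2M the lowest nuclear genes were HPRT1 of purine salvage and SDHD of respiratory complex II (both −4.48), LRRC40 (−4.45), MORF4L2 (−4.20), ARF4 (−4.08), CRYZ (−4.04), TPT1 (−3.96), ENOPH1 (−3.95) and the nucleolar protein NPM1 (−3.86). The median over 9099 genes was 0.44, and relative to it CDCP1 was at 1.60, STC1 at −0.73 and NSUN2 at −0.56. Without a pseudocount, the intervals on this relative scale were 1.57 to 1.91 for CDCP1, −1.67 to −0.67 for STC1 and −1.02 to −0.53 for NSUN2.

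Messages described before as NSUN2 substrates lay at percentile 99.96 in vehicle cells, with 10 of 18 members at least 2-fold higher and 3 lower. LRRC8A, a subunit of volume-regulated anion channels (1.82), HDGF, a growth factor (1.79), IRF3, a transcription factor of antiviral responses (1.77), and GRB2, an adaptor of growth factor receptors (1.49), led the list. Mitochondrially encoded genes lay at percentile 0, where 13 of 15 members, all of them messages, were lower and 0 higher, while MT-RNR2 and MT-RNR1 stood at 0.73 and 0.23. Interferon and inflammatory genes lay at 1.01, with 4 of 10 lower and 1 higher. The chemokines CXCL8 and CCL20 had 151 and 80 reads in the input against 0 and 1 in the IP, and CCL2 and CXCL1 were at −1.14 and −1.04. Small noncoding RNA lay at 0.47, with 4 of 6 lower and 1 higher, but on few reads, such as 17 and 3 for RNY1 and 23 and 6 for RN7SL1. By counts relative to the median gene, 5 substrates were higher and 3 lower, and 0 interferon and inflammatory genes higher and 5 lower. The call ended for NSUN2 messenger RNA substrates described before with pseudocount 0.1 (percentile 97.19), for interferon and inflammatory genes with pseudocount 5 (2.89) and for vault and other small noncoding RNA with lists matched on gene length (4.73). All 4 lists kept their side of the median gene under the other scalings.

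The remaining 18 lists were inside the bounds in vehicle cells. On FPKM as deposited, more members were higher than lower for secretory and folding genes (8 and 2 of 18, CALR 1.77), perineural invasion (7 and 2 of 18, CDCP1 2.04, SEMA3C −1.87), matrix and epithelial mesenchymal transition (6 and 1 of 15, TGFBI 2.08, CLDN1 −1.79), lactate transport and lactylation (6 and 2 of 20, SLC16A3 1.89, SIRT1 −1.79), the integrated stress response (5 and 3 of 17, TRIB3 2.58, MTHFD2 −1.78), proliferation (5 and 4 of 21, MKI67 2.86, PCNA −2.54) and ductal identity (5 and 4 of 15, KRT19 1.60, S100A11 −2.18). The same held for immediate early genes (4 and 2 of 11, KLF6 1.78, CCN1 −2.22), cholesterol synthesis (3 and 2 of 12, SC5D −1.50), glycolysis (3 and 1 of 11, PKM 1.35, PGK1 −1.22) and histones (2 and 1 of 9, H2AC6 −1.41). More were lower for ribosomal proteins (4 higher and 20 lower of 73, RPSA 1.80, RPL26 −2.95), nuclear encoded oxidative phosphorylation (3 and 7 of 38, UQCRC1 1.90, SDHD −4.48), oxidative stress (0 and 3 of 8, TXN −1.93) and m5C proteins (1 and 2 of 8, NSUN5 1.07, SRSF2 −2.15). Numbers were equal for hypoxia (1 and 1 of 9, ANGPTL4 1.53, INSIG2 −1.005), osmotic stress (1 and 1 of 7, NFAT5 1.10, SLC38A2 −2.37) and nuclear long noncoding RNA (2 and 2 of 12, TUG1 1.26, MALAT1 −3.70). Relative to the median gene, at 0.44, higher members stayed more frequent for perineural invasion (4 and 2), the integrated stress response (5 and 3) and histones (2 and 1), and were equal for lactate transport and lactylation (2 and 2). On that scale lower members were more frequent for folding (5 higher and 6 lower), matrix (1 and 3), proliferation (3 and 4), ductal identity (2 and 8), immediate early genes (1 and 2), cholesterol synthesis (2 and 4) and glycolysis (0 and 2). The same held for ribosomal proteins (1 and 31), oxidative phosphorylation (3 and 13), oxidative stress (0 and 3), m5C proteins (0 and 2), hypoxia (1 and 3), osmotic stress (0 and 2) and nuclear long noncoding RNA (0 and 4). The medians of the integrated stress response, osmotic stress and folding lists changed side between scalings.

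Across all genes of vehicle cells, 2509 were at least 2-fold higher and 1392 at least 2-fold lower in the IP (64.3% higher). The split was 4513 and 1334 (77.2%) with FPKM sums set equal, and 1124 and 2172 (34.1%) relative to the median gene.

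The lactate IP was compared with the lactate input in the same way. MLEC was highest at 2.76, from FPKM 2.25 to 21.01 (3.22 without a pseudocount, 95% interval 2.99 to 3.46), followed by BAZ1B (2.42), the potassium channel KCNK6 (2.39), PRRC2C (2.38), PMEPA1, an inhibitor of TGF-β signalling (2.36), and MAP1B (2.35). CDCP1 was again enriched, at 1.47, from FPKM 3.81 to 12.4 (277 and 1222 reads). STC1 stood at 0.25 (53 and 98 reads) and NSUN2 at −0.36 (114 and 102 reads). MT-ND2 was lowest at −7.40, and outside the mitochondrial genome HPRT1 was lowest at −4.60, with TPT1 at −4.47, SDHD at −4.40 and NPM1 at −4.33. Here too the rank rests on the pseudocount, since without it LRRC40 (−5.67) and CRYZ (−5.40) lay under HPRT1 (−5.03).

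DGCR6L (2.27), the adaptor subunit AP3D1 (2.26), the GTPase HRAS (2.202) and the chromatin remodelling subunit SMARCC1 (2.19) were the other highest genes. The other lowest were MT-CYB (−6.89), MT-ATP8 (−6.88), MT-ATP6 (−6.77), MT-ND4 (−6.62), MT-ND6 (−6.53), MT-ND1 (−6.09), MT-CO3 (−5.99), MT-ND3 (−5.97) and MT-ND5 (−4.96), and outside the mitochondrial genome MORF4L2 (−4.27), CRYZ (−4.14), LRRC40 (−4.02), SMIM15 (−3.91), TM4SF1 (−3.80) and B2M (−3.79). The median over 7170 genes was −0.10. Relative to it CDCP1 was at 1.57 (interval without a pseudocount 1.68 to 2.06), STC1 at 0.35 (0.12 to 1.12) and NSUN2 at −0.27 (−0.83 to −0.03). The value of NSUN2 turned to 0.39 when only genes with FPKM of at least 5 were compared.

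NSUN2 substrates described before lay at percentile 99.6 in lactate cells, with 4 of 14 members higher and 1 lower, led by GRB2 (1.34), QSOX1 (1.26), IRF3 (1.24) and the glycolytic enzyme PKM (1.17). Mitochondrially encoded genes lay at 0, with the 13 messages lower and MT-RNR1 and MT-RNR2 at 0.97 and 0.60. By counts relative to the median gene, 6 substrates were higher and 1 lower. Each of these lists kept its side of the median gene under the other scalings.

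The other 20 lists were inside the bounds in lactate cells. On FPKM as deposited, lower members were more frequent for ribosomal proteins (2 higher and 31 lower of 69, RPSA 1.37, RPS24 −3.39), nuclear encoded oxidative phosphorylation (3 and 13 of 37, UQCRC1 1.74, SDHD −4.40), ductal identity (3 and 7 of 15, KRT80 1.23, S100A6 −2.70), proliferation (2 and 5 of 20, MKI67 2.09, CDK1 −2.87), secretory and folding genes (3 and 5 of 18, CALR 1.53, DNAJB11 −1.22), oxidative stress (0 and 4 of 8, TXN −1.81), cholesterol synthesis (2 and 4 of 11, MSMO1 −1.48) and nuclear long noncoding RNA (0 and 3 of 11, MEG3 0.82, MALAT1 −3.97). Lower members also outnumbered higher ones for hypoxia (1 and 3 of 8, ANGPTL4 1.42, BNIP3L −1.41), lactate transport and lactylation (1 and 3 of 15, SLC16A3 1.47, SIRT1 −2.00), interferon and inflammatory genes (1 and 2 of 8, ISG15 1.01), matrix and epithelial mesenchymal transition (0 and 2 of 15, ITGA5 0.90, CLDN1 −2.74), m5C proteins (0 and 2 of 6, SRSF2 −2.07), osmotic stress (0 and 1 of 7, SLC38A2 −2.48), histones (0 and 3 of 7, H1-2 0.76) and small noncoding RNA (0 and 3 of 6). Higher members led for the integrated stress response (5 and 3 of 16, TRIB3 2.07, PSAT1 −1.91), perineural invasion (3 and 2 of 14, CDCP1 1.47, SEMA3C −3.05) and glycolysis (2 and 1 of 9, TPI1 1.24, PGK1 −1.33), and were equal for immediate early genes (1 and 1 of 8, KLF6 1.26, CCN1 −2.62). Relative to the median gene, folding genes turned to 5 higher and 3 lower, and cholesterol synthesis and lactate transport and lactylation to 3 and 3 each, while the other lists kept the direction of their counts. The medians of the osmotic stress, proliferation, histone, folding and small noncoding RNA lists changed side of the median gene between scalings.

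In lactate cells 1145 genes were at least 2-fold higher and 1673 at least 2-fold lower in the IP (40.6% higher). With median ratios the split was 2346 and 1433 (62.1%), with equal totals 3001 and 1193 (71.6%), with FPKM sums set equal 2152 and 1807 (54.4%), and relative to the median gene 1381 and 1472 (48.4%).

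Enrichment in the NSUN2 IP was compared gene by gene between the conditions. Across 6824 genes the enrichments had a Pearson r of 0.899 and a Spearman rho of 0.897, and Pearson r was 0.896 without mitochondrial genes; genes are not independent replicates, so no p is given. MLEC, PRRC2C, BAZ1B and MAP1B were among the 10 highest in both. Of 1972 genes enriched at least 2-fold in vehicle cells and 1006 in lactate cells, 891 were enriched in both, against 291 for independent lists. Of 1248 and 1582 depleted genes, 1087 were depleted in both, against 289, and 28 genes went opposite ways.

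**Figure D2:**
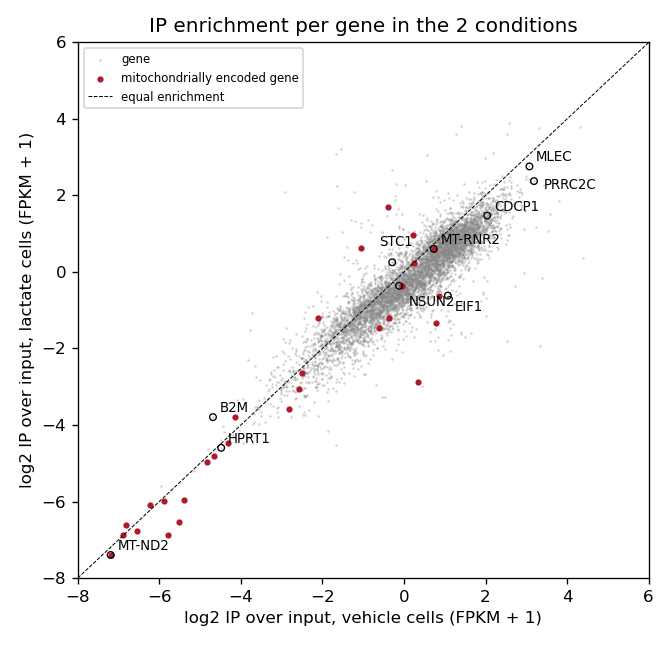
Log2 ratio of IP over input FPKM for each gene in vehicle cells (horizontal axis) and lactate cells (vertical axis), with mitochondrially encoded genes in red and equal enrichment as a dashed line. Enrichments rise together (Pearson r 0.899), but with medians of 0.44 in vehicle and −0.10 in lactate cells most points lie below the line, with PRRC2C and MLEC at the upper right and MT-ND2 at the lower left.

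The difference between the enrichments addresses whether RNA was more or less enriched in the NSUN2 IP under lactate. TGFBI, a secreted matrix protein induced by TGF-β, had FPKM 6.09 in the input and 28.9 in the IP of vehicle cells but 5.57 and 7.51 in lactate cells, a change of −1.70. HSCB, a chaperone of iron-sulfur cluster assembly (−1.74), CCDC34 (−1.70), the translation initiation factor EIF1 (−1.69), the fatty acid enzyme ECH1 (−1.65) and the complex III subunit UQCR11 (−1.65) were also among the lowest. RIDA, a deaminase of reactive imines, was highest at 1.52, but on 20 and 47 IP reads, followed by SDHAF3, an assembly factor of complex II (1.33), RPE (1.29) and the GTPase RHEB (1.21). The median over 9445 genes was −0.36. Relative to it STC1 was at 0.90 and CDCP1 at −0.21. Nuclear genes had 13.9% of the lactate IP against 20.9% of its input, and 30.3% against 31.3% in vehicle cells. The median of −0.36 as deposited contains this loss of share and does not by itself show weaker enrichment.

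Without a pseudocount, STC1 was at 1.47 relative to the median (95% interval 0.79 to 2.15), CDCP1 at −0.17 (−0.42 to 0.08) and NSUN2 at 0.04 (−0.42 to 0.50), so that only for STC1 did counting error leave out the median gene. NSUN2 stood at 0.11 with a pseudocount, and at −0.16 without a filter on low values. The other lowest genes were PGP (−1.57), SURF2 (−1.55), SCAND1 (−1.54) and LEO1 (−1.53), and the other highest C15orf48 (1.12), PRPS2 (1.01), RPP40 (1.00), TMEM69 (1.00), TMEM14A (0.95) and LIPT1 (0.94).

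In this comparison 2 lists lay above the range of random lists and 0 below. Mitochondrially encoded genes lay at percentile 99.4, with 0 of 15 members past 2-fold upwards and 2 downwards (1 and 0 relative to the median gene), and MT-RNR1 (0.74), MT-CO2 (0.36), MT-ND4 (0.20) and MT-ND1 (0.14) were highest. Small noncoding RNA lay at 97.96, with 1 of 7 higher and 1 lower (2 and 1 relative to the median gene), on few reads, such as 0 and 3 IP reads for RNY3 in vehicle and lactate cells. Matched on gene length and not on FPKM, neither call held, at percentile 86.085 for mitochondrially encoded genes and 68.82 for vault and other small noncoding RNA. The medians of both lists stayed above the median gene under the other scalings.

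The other 20 lists lay inside the bounds. On FPKM as deposited, lower members outnumbered higher ones for ribosomal proteins (8 of 73 lower, 0 higher, RPL34 −1.41), matrix and epithelial mesenchymal transition (3 of 15, 0 higher, TGFBI −1.70, PLAU 0.31), histones (3 of 10, 0 higher, H1-2 0.41), oxidative phosphorylation (2 of 38, 0 higher, NDUFA1 −1.10, ATP5MC1 0.74) and proliferation (2 of 21, 0 higher, MCM7 −1.29, CCNB2 0.27). A single member was lower and 0 higher for hypoxia (of 9, LOXL2 −1.07), the integrated stress response (of 17, SHMT2 −1.03, CHAC1 0.46), perineural invasion (of 18, SEMA3C −1.18, STC1 0.54), nuclear long noncoding RNA (of 12, SNHG6 −1.46, NEAT1 0.26) and secretory and folding genes (of 18, DNAJC3 −1.06, HERPUD1 0.51). MYC alone was higher in the immediate early list (1 of 11) and among NSUN2 substrates (1 of 18, LRRC8A −0.99), at 1.56 on 112 input and 3 IP reads in vehicle cells against 11 and 40 in lactate cells. No member passed 2-fold among 8 m5C proteins (YTHDF2 −0.82), 20 genes of lactate transport and lactylation (KAT2A −0.99), 11 of glycolysis (GAPDH 0.65), 7 of osmotic stress (AKR1B1 −0.92), 9 of oxidative stress (TXNRD1 −0.93), 12 of cholesterol synthesis, 10 interferon and inflammatory genes (CXCL1 0.49) and 15 of ductal identity (MUC1 −0.88). Relative to the median gene, at −0.36, 1 member was lower and 0 higher for each of ribosomal proteins, matrix, histones and nuclear long noncoding RNA. On that scale 1 was higher and 0 lower for oxidative phosphorylation, glycolysis, immediate early genes and NSUN2 substrates, and 0 members of the other lists passed 2-fold. The ductal identity, lactate, oxidative phosphorylation and folding lists changed side of the median gene between scalings. By count, 287 genes were at least 2-fold higher and 903 lower (24.1% higher), against 524 and 379 (58.0%) with median ratios, 585 and 442 (57.0%) with equal totals, and 483 and 310 (60.9%) relative to the median gene.

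Lactate IP over vehicle IP, with no reference to the inputs, is the comparison of the authors' peak table. ATP5F1E was lowest at −3.09, from FPKM 90.2 to 9.74, with ATP5PF at −2.87, EIF1 at −2.78, the keratin KRT10 at −2.74, UBL5 at −2.67 and NDUFA1 at −2.62. EGR1 was highest at 0.97, from FPKM 4.94 to 10.6, with ZFP36, a factor that promotes mRNA decay, at 0.82 and B2M at 0.35. The median over 8366 genes was −0.74, and relative to it STC1 was at 1.14, CDCP1 at 0.40 and NSUN2 at −0.12. CDCP1 turned to −0.11 without a filter and NSUN2 to 0.15 with FPKM of at least 5. NDUFB1 (−2.56), TMA7 (−2.49), SEC61G (−2.32) and NOP58 (−2.29) completed the lowest, and CCN1 (0.05), CDK2AP2 (0.00), MYL12A (−0.01), RRAS (−0.05), CCL2 (−0.06), HIGD1A (−0.07) and SLC2A4RG (−0.10) the highest. Past 2-fold were 137 genes upwards and 2317 downwards (5.58% higher), against 436 and 225 (66.0%) with median ratios, 516 and 298 (63.4%) with equal totals and 306 and 218 (58.4%) relative to the median gene. Nuclear genes had 13.9% of the lactate IP and 30.3% of the vehicle IP, which by itself lowers their FPKM.

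Peaks of each IP over its own input place the enrichment within genes. The vehicle list held 95785 peaks covering 31.2 Mb in 16674 genes, with a median length of 241 bp and a median fold of 3.03. The lactate list held 48104 peaks covering 14.4 Mb in 12114 genes, with a median length of 225 bp and a median fold of 3.24. Introns held 56.1% of vehicle and 57.7% of lactate peaks, exons 21.8% and 19.8%, 3′ UTRs 12.9% and 15.4%, intergenic regions 7.54% and 5.74%, and 5′ UTRs 1.63% and 1.35%. The lists are permissive, with q under 0.05 at 46524 vehicle peaks (48.6%) and 20549 lactate peaks (42.7%), of which introns held 47.7% and 46.9% and 3′ UTRs 18.8% and 23.5%.

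Of vehicle peaks, 27.8% overlapped a lactate peak (95% Wilson interval 27.5% to 28.1%), and of lactate peaks 56.4% overlapped a vehicle peak (56.0% to 56.8%). Peaks in 3′ UTRs were shared most, at 43.8% of vehicle and 79.4% of lactate peaks, and intergenic peaks least, at 12.6% and 34.1%, with exons at 34.5% and 71.6%, 5′ UTRs at 26.6% and 66.0% and introns at 23.6% and 47.1%. Genes with a peak in both lists numbered 10959, in the vehicle list alone 5715 and in the lactate list alone 1155. Ranked by the authors' q, 82.6% of vehicle peaks were shared in the strongest of 10 equal parts and 5.53% in the weakest.

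**Figure D3:**
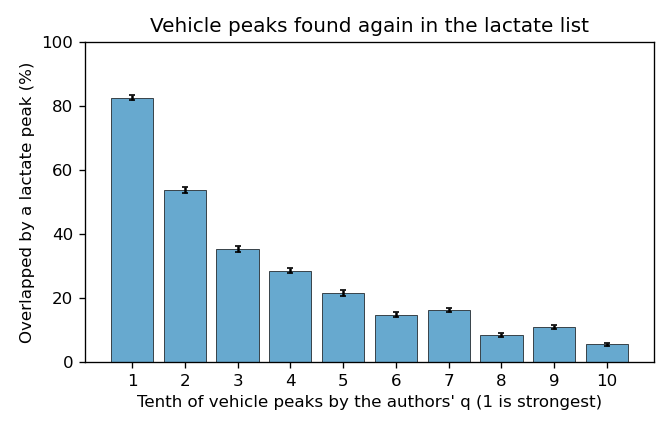
Percent of vehicle peaks overlapped by a lactate peak (vertical axis) in 10 equal parts of the vehicle list ranked by the authors' q (horizontal axis), with 95% Wilson intervals as error bars. The share is 82.6% in the strongest part and 5.53% in the weakest.

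CDCP1, on chromosome 3 of GRCh38, had 19 vehicle and 14 lactate peaks, of which 4 and 4 were in the 3′ UTR, 4 and 3 in exons and 11 and 7 in introns. Its strongest fold was in an exon, at 45088902 to 45089329 with fold 18.2 in vehicle cells and 45088910 to 45089325 with fold 30.1 in lactate cells. In the 3′ UTR a peak at 45082277 to 45082956 had fold 5.54 in vehicle cells, and the lactate peak at 45082286 to 45082873 had fold 2.289. STC1, on chromosome 8, had a 5′ UTR peak in both, at 23854572 to 23854804 with fold 7.46 in vehicle cells and 23854573 to 23854854 with fold 4.25 in lactate cells. A second STC1 peak, in the 3′ UTR at 23843297 to 23843532, was listed in lactate cells only, with fold 2.11 and q 0.133. NSUN2, on chromosome 5, had 4 vehicle and 2 lactate peaks, among them a 3′ UTR peak at 6607213 to 6607496 with fold 3.64 and q 0.0193 in vehicle cells.

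**Figure D4:**
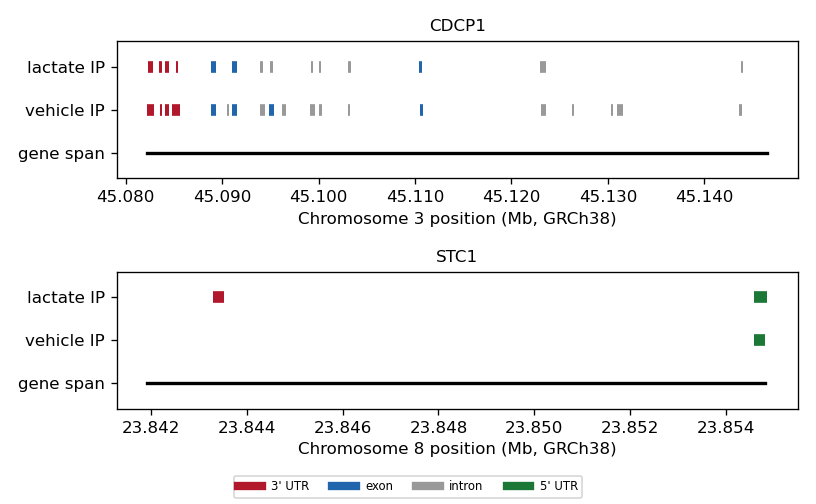
Peaks of the vehicle and lactate lists along CDCP1 on chromosome 3 and STC1 on chromosome 8 (horizontal axes, GRCh38 positions), coloured by annotated feature. CDCP1 has 19 vehicle and 14 lactate peaks, and STC1 has 1 and 2.

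The authors' deposited table set the IP libraries against each other at 116484 peaks, of which 69138 were vehicle-only, 26381 common and 20965 lactate-only. P in the authors' deposited table is 0.5 times a point probability at most peaks and not a p-value, so thresholds on it carry no error rate. At M of at least 1 and P under 0.01, the authors' deposited table had 1467 peaks higher and 4202 lower in the lactate IP. By feature, the authors' deposited table gave 1120 higher and 1580 lower in introns, 140 and 1464 in exons, 118 and 898 in 3′ UTRs, 10 and 88 in 5′ UTRs, and 79 and 172 in intergenic regions. The lowest M in the authors' deposited table was at a 3′ UTR peak of PTCD2, a mitochondrial RNA processing factor (chromosome 5, 72363948 to 72364408, M −5.46, 0 lactate and 46 vehicle reads). NAA15 (−5.43), an exon of PRRC2C (−5.28), ZSWIM6 (−5.25), PPIP5K2 (−5.21), SND1 (−5.03), PKP4 (−4.95), LRBA (−4.95), PIK3R4 (−4.43) and ZNF814 (−4.40) followed in the authors' deposited table. The highest M in the authors' deposited table was at an intron peak of KATNBL1 (chromosome 15, 34201124 to 34201781, M 4.03, 29 lactate and 1 vehicle reads), then PDIA5 (3.81), VCL (3.75), MAGED1 (3.75), RASAL2 (3.74), SCAPER (3.68), ST6GALNAC6 (3.68), ONECUT3 (3.62), ACTN4 and CAMKMT (both 3.597). The peak in MT-RNR2 had M 3.83 in the authors' deposited table, on 7681346 lactate and 5927087 vehicle reads. Its log2 read ratio was only 0.37, and the rest of that M came from a line in A, described below, at A 21.7. The reads and ratio of this peak rest on extending that line far past the peaks on which it was fitted.

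For STC1, the authors' deposited table gave M 1.43 and P 0.00153 at the 3′ UTR peak (42 lactate and 21 vehicle reads) and M 0.22 at the 5′ UTR peak (15 and 16 reads). CDCP1 in the authors' deposited table had M 0.67 and P 5.60e-08 at the 3′ UTR peak on 405 lactate and 557 vehicle reads. In the authors' deposited table M was 1.01 at the exon peak, and 1.07 with P 1.29e-08 at an intron peak on 219 and 199 reads. That intron peak was listed in vehicle cells only, with fold 4.25 and q 0.00224. Of the 19 CDCP1 peaks in the authors' deposited table, 13 had M above 0 and 6 below, such as M −0.85 at an intron peak on 12 and 29 reads, and at P under 0.01 these were 4 and 0. NSUN2 peaks had at most 6 reads. Median reads per peak in the authors' deposited table were 5 in the lactate and 7 in the vehicle IP, and 45.1% of peaks had under 10 reads in both together. The line in A fitted to recover the reads, by which M departed from their log2 ratio, had intercept −0.20 and slope 0.17. At 9248 peaks of the authors' deposited table M and the read ratio therefore had opposite signs. Scalings chosen after seeing the data put a constant in place of that line. They also put a binomial tail probability of the recovered reads, under 0.01, in place of the deposited P. There were then 11954 peaks higher and 2108 peaks lower with a constant from nuclear reads, and 4928 and 6531 with a constant from common peaks. Scaling and P were changed together and neither was changed alone, so the part of each in these counts was not worked out.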

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

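The demand that opposite directions hold both as deposited and relative to the median gene, each beyond its counting interval, was a test not fixed before the data were examined, and this part reports no other test.

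Among 90 named genes, 5 were enriched in the NSUN2 IP of vehicle cells and depleted in that of lactate cells. The rule for named genes had picked CCDC34, EIF1, ECH1 and SCAND1 for a low change in enrichment and NOP58 for a low ratio of lactate IP over vehicle IP, so the count says nothing about genes at large. The median gene moved the same way, from 0.44 to −0.10. Other genes were opposite on 1 scale only. LEO1 (0.39 and −1.15), SEC61G (0.55 and −0.67) and CCN2 (0.50 and −0.31) were so as deposited. STC1 (−0.73 and 0.35) and CDK2AP2 (−0.58 and 0.57) were so relative to the median gene, in the other direction. The difference between conditions was not tested, since each group has 1 library.

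EIF1, which selects start codons in translation initiation, had a log2 enrichment of 1.08 in vehicle cells and −0.62 in lactate cells, a difference of −1.69. ECH1, an enzyme of fatty acid oxidation, had 1.01 and −0.64, a difference of −1.65. NOP58, a core protein of small nucleolar ribonucleoproteins, had 0.76 and −0.70, a difference of −1.47. CCDC34 had 0.71 and −0.996, a difference of −1.70. SCAND1 had 0.82 and −0.72, a difference of −1.54. No biological or technical explanation was tested for these genes.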

How the results depend on the processing

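Random lists matched on gene length and constant scaling of the peak comparison were tests chosen only after the result was seen. Matching on length took the place of matching on FPKM, so calls that moved with it are not due to length for certain. Over the settings tried, 42 of 143 counts and shares stayed within 1.5 times or their interval and 101 moved. Of 440 list percentiles, 405 kept their call, 19 lost it and 16 gained it. Of 945 values of named genes relative to the median gene, 556 stayed within their counting interval, 383 moved with the same sign and 6 changed sign. The cause was not tested unless a reason is given. No paired analysis was possible because each group has 1 library. Among 1319 genes chosen for at least 200 reads in every library, counting error made up 9.01% of the variance of the input change, 0.273% and 0.615% of that of the vehicle and lactate enrichments, 4.32% of that of the IP change and 8.10% of that of the change in enrichment. Genes with fewer reads have a larger counting error, and the spread across genes does not stand for that between replicates. All values rest on 1 library per group, which no setting can change.

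Counts of genes higher and genes lower moved as follows, in the order input change, vehicle enrichment, lactate enrichment, IP change and change in enrichment. A pseudocount of 0.1, which enlarges ratios of low values, gave 1134 genes lower in the inputs, 3786 genes higher with vehicle, 2031 genes higher with lactate, 4552 genes lower between IPs, and 598 genes higher and 2100 genes lower for the change. A pseudocount of 5, which shrinks them, gave 9 and 67, 556 and 569, 110 and 593, 5 and 502, and 18 and 99 genes higher and lower. FPKM of at least 5, which leaves fewer genes, gave 17 and 221, 1182 and 911, 377 and 971, 15 and 1470, and 44 and 389. The 1.5-fold threshold, which admits more, gave 181 and 2128, 4104 and 2115, 2174 and 2544, then 5504 genes lower between IPs, and 532 and 2898. Protein-coding genes alone gave 2 and 171 for the inputs, 0 genes higher between IPs, and 20 and 378 for the change.

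Scaling by median ratios gave 208 genes higher and 103 genes lower in the inputs, 2346 higher with lactate, 436 and 225 between IPs, and 524 and 379 for the change. Equal totals without mitochondrial genes and the 20 highest genes gave 192 and 101, 3001 higher with lactate, 516 and 298, and 585 and 442. FPKM sums set to 1000000 gave 211 and 809 for the inputs, 4513 higher with vehicle, 2152 higher with lactate, 269 and 4621 between IPs, and 509 and 2081 for the change. These scalings shift every gene of a library by a factor, which moves genes across the threshold.

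The Pearson r between the enrichments was 0.852 with pseudocount 0.1, 0.916 with pseudocount 5, 0.827 with no filter, 0.948 with FPKM of at least 5, 0.894 with equal totals and 0.865 with equal FPKM sums. The number of genes enriched in both was 1696 with pseudocount 0.1, 99 with pseudocount 5, 354 with FPKM of at least 5, 1828 with equal totals and 1706 with equal FPKM sums, and genes depleted in both 466 with pseudocount 5 and 704 with FPKM of at least 5.

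Among lists in the inputs, matching on length moved nerve growth, axon guidance and perineural invasion to percentile 97.8, ductal adenocarcinoma and PANC-1 identity to 0.22, NSUN2 messenger RNA substrates described before to 1.62 and cytosolic ribosomal protein to 0, past the bounds, and epithelial mesenchymal transition and matrix to 89.8, vault and other small noncoding RNA to 88.5 and replication dependent histone to 6.03, inside them. Pseudocount 0.1 moved epithelial mesenchymal transition and matrix to 94.9 and nuclear long noncoding RNA to 96.4. Pseudocount 5 moved integrated stress response to 16.1, nuclear long noncoding RNA to 94.8, ductal adenocarcinoma and PANC-1 identity to 0.23 and cytosolic ribosomal protein to 0.35. Median ratios moved osmotic stress response to 93.9, epithelial mesenchymal transition and matrix to 89.9 and nuclear long noncoding RNA to 79.4. Equal totals moved osmotic stress response to 94.4, epithelial mesenchymal transition and matrix to 90.8, nuclear long noncoding RNA to 81.8 and nerve growth, axon guidance and perineural invasion to 97.54.

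In the vehicle enrichment, matching on length moved ductal adenocarcinoma and PANC-1 identity to 0.58, cytosolic ribosomal protein to 0 and nuclear encoded oxidative phosphorylation to 0.17, past the lower bound, and vault and other small noncoding RNA to 4.73, inside it. Pseudocount 0.1 moved NSUN2 messenger RNA substrates described before to 97.2, and pseudocount 5 moved interferon and inflammatory to 2.89. In the lactate enrichment, matching on length moved ductal adenocarcinoma and PANC-1 identity to 1.22 and cytosolic ribosomal protein to 0, and pseudocount 0.1 moved integrated stress response to 98.2. For the change in enrichment, matching on length moved vault and other small noncoding RNA to 68.8 and mitochondrially encoded to 86.1, pseudocount 0.1 moved integrated stress response to 98.4 and interferon and inflammatory to 98.9, pseudocount 5 moved vault and other small noncoding RNA to 85.1, and median ratios moved integrated stress response to 98.2.

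Signs of 6 named values changed, on the scale relative to the median gene. STC1 in the inputs went to −0.0232 with no filter, CDCP1 between IPs to −0.11 with no filter, and NSUN2 in the change of enrichment to −0.16 with no filter and −0.0082 with equal totals. NSUN2 went to 0.39 in the lactate enrichment and 0.15 between IPs with FPKM of at least 5. A filter leaves the gene's own value and changes the median gene, which by construction gives the shifts with a filter. The cause of the shift with equal totals was not tested.

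At or above the median −log10 q of both lists together there were 49169 vehicle IP peaks and 25159 lactate IP peaks, with fold of at least 4 there were 31079 and 16981. The percent intronic, vehicle IP, was 47.9 and 50.5 under these settings, and the percent intronic, lactate IP, was 50.6 and 53.9. No coordinates were listed more than once, so that setting changed nothing. The overlapped percent of vehicle IP peaks and percent of lactate IP peaks were 25.6% and 51.9% with 50% of the shorter peak, 19.1% and 38.0% with 50% of both, 33.1% and 65.6% among the more significant peaks, and 44.4% and 45.5% with equal numbers of the strongest. In the authors' deposited table there were 647 peaks higher and 2137 peaks lower with M of at least 2, 90 and 254 with P under 1e-05, and 396 and 1394 with that P adjusted by Benjamini-Hochberg under 0.05. As that column does not hold p-values, the adjusted counts have no meaning as error rates. Constant scaling, with a binomial tail probability of the recovered reads in place of that P, gave 11954 and 2108 by nuclear reads. By common peaks it gave 4928 and 6531.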

Other observations

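The scan of annotated gene groups, the comparison of RNA classes, the test of weaker NSUN2 binding and both tests of mitochondrial RNA were chosen only after the result was seen.

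Gene Ontology groups of 15 to 500 members were set against 1000 random lists matched on mean FPKM, with FPKM as deposited, and neither other scalings nor matching on gene length were tried for these groups. In the inputs, 4 of 1035 groups lay above all random lists and 11 below all. Among the groups below were ATP synthesis coupled proton transport (−0.41 relative to the median gene, lowest at ATP5F1E, ATP5PF and ATP5MC3), NADH dehydrogenase activity (−0.32, NDUFA1, NDUFA4 and NDUFB1), mitochondrial translational elongation (−0.21), rRNA processing (−0.22), mRNA capping (−0.29) and nucleotide-excision repair (−0.23, XPA, GTF2H5 and RFC4). Genes of up to 2390 bp lay at −0.23 in the same comparison, as far down as several of these groups. Measured from their matched random lists instead, proton transport was at −0.29, NADH dehydrogenase activity at −0.25 and translational elongation at −0.17. On that scale rRNA processing was at −0.16, mRNA capping at −0.30 and nucleotide-excision repair at −0.24. Cell adhesion (0.10), integrin binding (0.13), ERK signalling (0.13) and heparin binding (0.12) lay above, each with CCN2 among its highest members. In the vehicle IP, 6 of 1309 groups lay above and 2 below. Here intermediate filament genes (log2 enrichment 1.25, highest at CLIP1, DSP and SLC1A4), regulators that limit type I interferon production (1.33, ILRUN, TRAF3IP1 and MAVS), activators of GTPases (1.07), histone binding (0.84) and endocytosis (0.84) lay above all random lists, and GDP binding (−0.60, RHEB, RAB5A and RAP1A) and neutrophil chemotaxis (−0.77, PPIA, CXCL8 and CCL20) below. In the lactate IP, 5 of 1086 groups lay above and 1 below. Here kinetochore genes lay below all (−1.01, CENPH, SEPTIN2 and DYNLT3), and genes of the outer plasma membrane face (0.51) and of chromosomes (0.43) above. For the change in enrichment, 1 of 1316 groups lay above, neutrophil chemotaxis (0.17), and 1 below, histone binding (−0.57). The change contains the vehicle enrichment with its sign turned, so a group extreme in vehicle cells tends to the other side of the change by noise alone, and both of these groups were extreme there. With that many groups scanned, some lie past all random lists by chance, and members are shared between groups.

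Classes of noncoding RNA also differed. Small nucleolar RNA, which guides modification of ribosomal RNA, had a median enrichment of 1.34 over 42 genes in vehicle cells and −0.06 over 34 genes in lactate cells. Small nuclear RNA of the spliceosome had 1.11 and 0.66, lncRNA 0.72 and 0.46, processed pseudogenes 0.19 and −0.54, and miscellaneous RNA 0.88 and 1.18. The median gene itself went from 0.44 to −0.10. Relative to it, vehicle and lactate values were 0.89 and 0.04 for small nucleolar RNA, 0.67 and 0.76 for small nuclear RNA, 0.28 and 0.56 for lncRNA, −0.25 and −0.45 for processed pseudogenes, and 0.44 and 1.28 for miscellaneous RNA, so that the order of the conditions depends on the scale for small nuclear RNA and lncRNA. These medians are on FPKM as deposited, and reads of host genes were not separated from them. For short RNA an FPKM of at least 1 can rest on few reads, as given above for the small noncoding RNA list. Reads per gene were not examined for these classes. These medians rest on different sets of genes in the 2 conditions. The change between conditions, taken within each gene, had a median of −1.06 over 56 small nucleolar RNA genes (−0.70 relative to the median gene). It was −0.68 over 114 small nuclear RNA genes (−0.32) and −0.39 over 746 lncRNA genes (−0.04). For 734 processed pseudogenes it was −0.50 (−0.14), and for 127 miscellaneous RNA genes 0.23 (0.58). In the inputs small nucleolar RNA was higher in lactate cells, with a median of 0.34 over 29 genes.

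On FPKM as deposited, MT-RNR2 and MT-RNR1 were higher in both IPs than in their inputs while mitochondrial messages were far lower. In vehicle cells, with the median gene at 0.44, MT-RNR1 (0.23) lay under it and MT-RNR2 (0.73) only 0.29 above. In lactate cells, with the median gene at −0.10, MT-RNR1 (0.97) and MT-RNR2 (0.60) both lay above it. Whole mitochondria carried along with their RNA as in the input would bring their messages too. The median log2 enrichment of the 13 messages was −5.79 in the condition where it was higher, which argues against carry-over in those proportions. It cannot decide for mitochondria that did not keep their messages through the IP. Dilution of all other RNA by MT-RNR2 would lower nuclear messages alike, but the median of mitochondrial minus that of nuclear messages was −6.21 in vehicle cells and −5.98 in lactate cells, which argues against it as the whole cause. Both expectations were written after the low mitochondrial messages had been seen, so neither outcome was open. Carry-over of mitochondrial ribosomes, or association of NSUN2 with mitochondrial ribosomal RNA, may remain, and neither was tested, since no library with a control antibody was analysed here.

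Introns held 56.1% of vehicle and 57.7% of lactate peaks, and 47.7% and 46.9% of those with q under 0.05. Genomic DNA would give peaks in silent genes, but introns of genes with FPKM of at least 1 held 73.9 vehicle peaks per Mb against 3.53 in 7515 undetected genes, 20.96 times as many, which argues against it. Scattered reads passing a loose threshold would not recur. The test took the 23482 lactate intron peaks that lay within the span of their protein-coding gene. Of all 53767 vehicle intron peaks, 10794 met one of these. This was 7.30 times the mean of 1478 over 20 random placements in the same genes (1411 to 1551). It argues against scattered reads as the source of all intron peaks. Most vehicle intron peaks did not recur, and for these the test does not decide. The placements were uniform along each gene and did not follow local read density. Unspliced RNA, bound by NSUN2 or carried along without it, is a candidate explanation that stays open and was not tested.

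The lactate list held fewer peaks than the vehicle list. Fewer nuclear reads in the lactate IP could give this, and then at least 90% of the strongest vehicle peaks should recur, whereas under 70% would have argued against it. The measured 82.6% lies between and does not decide. Weaker binding of NSUN2 under lactate should lower reads at common peaks more than all nuclear reads, but these were 0.49 higher on the log2 scale relative to nuclear reads, and nearly level at 2685 common peaks with A of at least 6 (−0.91 against −0.97). That value excludes nothing, because the scaling absorbs a change common to all RNA. These 2 explanations therefore cannot be told apart with these values, which also rest on 1 library per group.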
